A study of Mus musculus with 63 samples.

How the data were processed

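RNA was sequenced from 4 cell populations sorted from orthotopic MMTV-PyMT mammary tumours of FVB/n mice after 4 treatments, with 63 libraries in all. Per the labels' protocols, cells were sorted by flow cytometry, RNA was amplified with an ultra-low-input SMARTer kit, libraries were made with Nextera XT, and paired reads of 50 cycles were generated on a HiSeq2500. Bowtie2 is the only program named in the submitters' processing notes, and its version, the genome build, the annotation and the counting rule are not given in the sources used here. Because no build is stated, no coordinates are printed.

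Each deposited file holds log2 values of RPKM (reads per kilobase of gene, scaled to the mapped reads of the library) computed by the authors, as the file headers and the values themselves show. Raising 2 to each value gave either 0.005 or a whole multiple of 0.01 RPKM, so the RPKM had been rounded to 2 decimals and zeros replaced by 0.005 before the logarithm was taken. Of all values, 35.4% lay at that floor. Each file lists 29489 genes by Ensembl ID, of which 17693 carry a symbol in the file. A further 8980 were named from the gene names table supplied with the reference, and 2816 remained unnamed. Of the symbols in the files, 17329 had their ID in that table and 16692 were identical there. A total of 475 genes shared a symbol with another ID.

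The files hold no counts, so depth was estimated from the steps between low RPKM values of 2679 genes with annotated lengths of 100 to 400 bp, where 1 read is a visible step. The estimates ran from 21370000 to 49750000 mapped reads per library, with a median of 25900000. In each library 86.61% to 93.79% of these low values lay within 0.1 read of a whole number, against 20% by chance. No interval for counting error was derived from these estimates, since amplified reads without molecular identifiers are not independent molecules.

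The plan, fixed before the data were examined, used a count model if the files held counts and limma on log2(value + 1) if they held normalised values only. The second branch applied. RPKM were restored from the deposited log2 values, genes with at least 1 RPKM in as many libraries as the smallest group held were kept, and limma 3.58.1 (R 4.3.3) with a mean-variance trend was fitted to log2(RPKM + 1). A separate model was fitted to the libraries of each cell type with treatment as the factor and no other term. No scaling between libraries was applied beyond the authors' RPKM. The number of genes tested was 13759 in endothelial cells, 11445 in macrophages, 13193 in CD8 T cells and 13562 in CD4 T cells.

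Each model gave 6 contrasts. A2V, anti-CD40 and their combination were each compared with IgG, the combination was compared with each single agent, and an interaction contrast tested whether A2V acted differently with and without anti-CD40. P-values were adjusted by Benjamini and Hochberg over the genes of a contrast, and an adjusted p under 0.05 counted as passing. They measure the spread between libraries, which the labels describe as independent tumours. Fold changes are log2 differences with their standard error, and levels are mean RPKM with the standard deviation over libraries.

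Gene lists were also fixed before the files were opened: 24 function lists and 19 marker lists with 588 symbols, of which 11 were absent from the files. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment covered all function lists and contrasts of a cell type, and marker lists formed a family of their own. For each list the members passing over all genes and the members passing when adjusted over the list alone were counted.

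Genes are named by a rule fixed in the same plan. It takes up to 10 of the largest rises and falls per contrast (5 for the interaction) that pass the adjusted p, have a mean log2 level of at least 3 and separate the groups completely, leaving out unnamed gene models and receptor segments. It adds up to 4 members with the smallest p from each function list, the antibody targets and their receptors, and marker genes as measures of purity. The planned level was in CPM units, and the same number was applied to log2(RPKM + 1). Other genes are named only where a count was 5 or fewer or a gene was singled out, with a statement that they were chosen after their values were seen.

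The procedure was tested on data simulated from the means and spreads of the real genes, with some genes shifted. It covered A2V and the combination against IgG in each of the 4 cell types. With a log2 shift of 1, between 32.84% and 70.15% of shifted genes were recovered per simulated comparison, with a shift of 2 between 83.58% and 97.01%, and with a shift of 3 between 93.94% and 98.48%. Between 3 and 12 of the 153 to 188 genes called were false. Camera found all 20 lists shifted by 0.5 in every simulated contrast, and 0 to 4 of 100 unchanged lists had a p under 0.05. Genes were drawn independently with many shifted, so no rate covers correlated genes or few changes.

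Alternatives were another pseudocount, no filter on low values, a median-of-ratios scaling, fits to the libraries of 2 groups only, a block for the numbered library set, leaving out each library in turn, leaving out the library least correlated with the others, and a covariate for macrophage marker level. Counts of passing genes were also compared with those from other splits of the same libraries. Red cell genes were compared with an exact permutation test. Values were processed with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and drawn with matplotlib 3.10.9.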

Results

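RNA was measured in 63 libraries of cells sorted from mouse mammary tumours. The tumours were grown orthotopically in FVB/n females from the MMTV-PyMT model, in which a viral oncoprotein drives mammary carcinoma. At a volume of 300 mm3 the mice were injected with antibodies, and cells were collected 5 days later. Control mice received 20 mg/kg mouse IgG1 and 4 mg/kg rat IgG2a. The A2V group received 20 mg/kg of A2V, a bispecific antibody against the angiogenic ligands VEGFA and ANGPT2, with 4 mg/kg rat IgG2a. The anti-CD40 group received 4 mg/kg of an agonist of CD40, a costimulatory receptor of antigen-presenting cells, with 20 mg/kg mouse IgG1, and the combination group received A2V and anti-CD40 at the same doses. From each treatment 4 populations were sorted, with 4 libraries per population and treatment, except for 3 endothelial libraries in the combination group.

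Estimated depth was 22720000 to 31520000 mapped reads in endothelial libraries, 24590000 to 33480000 in macrophages, 21370000 to 32050000 in CD8 T cells and 21370000 to 49750000 in CD4 T cells. Between 9785 and 13067 genes per library reached 1 RPKM. Across genes, which are not independent replicates, libraries of a group correlated with r between 0.815 and 0.977.

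The sorted populations carried their own markers. Endothelial cells, gated as CD31-positive and CD45-negative, held 759 ± 174 RPKM (SD, n = 15) of Pecam1, which encodes CD31. Macrophages, gated on CD45, CD11b and F480, held 391 ± 150 RPKM (n = 16) of Adgre1, the gene of F480. The T cell receptor component Cd3e stood at 1380 ± 108 RPKM in the CD8 gate and 926 ± 148 in the CD4 gate (n = 16 each), Cd8a at 787 ± 138 in the CD8 gate and 2.23 in the CD4 gate, and Cd4 at 310 ± 66 in the CD4 gate. Markers of other cells were also present. The CD4 gate held 77 ± 42.5 RPKM of Adgre1 and 1940 ± 1580 of the macrophage lysozyme Lyz2, against 5.79 and 246 in the CD8 gate. The mean log2 level of plasmacytoid dendritic cell markers was 5.38 ± 0.95 in the CD8 gate, 4.53 ± 0.56 in the CD4 gate, 0.96 in macrophages and 0.64 in endothelial cells. Tumour epithelial markers stood at 2.73 in endothelial cells, 1.5 in macrophages, 2.28 in CD8 T cells and 1.91 in CD4 T cells.

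**Figure D1:**
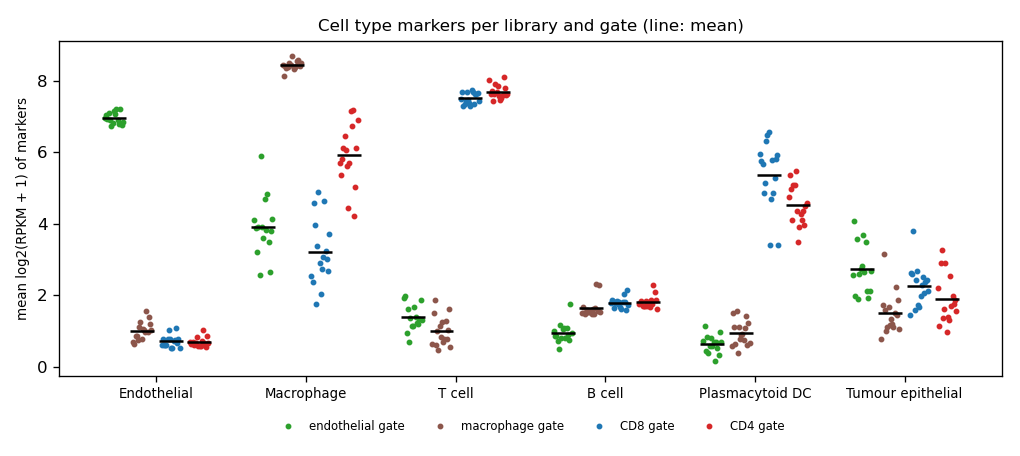
Mean log2(RPKM + 1) of 6 marker lists in each library, by sorted population; each point is 1 library. The macrophage list averages 8.44 in the macrophage gate, 5.92 in the CD4 gate, 3.9 in the endothelial gate and 3.22 in the CD8 gate.

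Over the 6 contrasts, camera at the preset correlation called 33 of 72 tests of a function list in endothelial cells, 48 of 78 in macrophages, 18 of 48 in CD8 T cells and 30 of 66 in CD4 T cells. Of these 129 calls 92 were upward and 37 downward, and 4 passed with an estimated correlation, each of the 4 in macrophages. In fits that each left out 1 library of the contrast, a check chosen after the data were seen, 60 of the 129 calls held every time. The lists described here are mainly those 60.

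In endothelial cells, A2V was compared with IgG to see what blockade of VEGFA and ANGPT2 changed in tumour vessels. Genes induced by interferon gamma stood higher with A2V in 27 of 28 measured cases, with a median log2 difference of 0.78. Of the 28, 17 rose when adjusted over the list alone, 0 rose over all genes tested and 11 did not pass. Cd274, which encodes the checkpoint ligand PD-L1, was at 12.9 ± 3.47 RPKM (SD, n = 4) with IgG and 34.7 ± 11.6 with A2V (log2 difference 1.34 ± 0.29, SE), and the guanylate-binding protein Gbp4 at 53 ± 9.66 and 110 ± 25.3. Irgm2, an immunity-related GTPase, was at 37.1 ± 9.51 and 72.9 ± 7.43, and the chemokine Cxcl10 at 57.2 ± 31.2 and 125 ± 23.2. The list passed at adjusted p = 7.43e-33 with camera, and adjusted p = 0.0786 with an estimated correlation. In the same libraries dissociation-stress markers stood higher (14 of 14, median 0.79, adjusted p = 9.88e-07, and adjusted p = 0.792 with an estimated correlation) and T cell markers lower (10 of 10, median -0.54, adjusted p = 1.21e-05, and adjusted p = 0.792 with an estimated correlation).

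Genes of antigen presentation by MHC class II were higher in 11 of 11 cases (median 1.05, adjusted p = 3.85e-09, and adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, Cd74, Ciita, H2-DMa, H2-DMb1 and H2-DMb2 rose, against 0 over all genes, and this count of 5 fell to 0 without A2V replicate 2, A2V replicate 4 or IgG replicates 2, 3 or 4. H2-DMa, which helps load peptides, was at 78.6 ± 42.3 RPKM with IgG and 176 ± 80.5 with A2V, and the invariant chain Cd74 at 2190 ± 595 and 6060 ± 4760 (n = 4 each), with 13107 in A2V replicate 2 alone against 2725 to 4625 in the others. Macrophage markers did not pass in this contrast (adjusted p = 0.442), but their mean log2 level was 4 ± 1.38 with A2V, up to 5.89 in that library, and 3.78 ± 0.4 with IgG. Targets of NF-kB were higher in 16 of 20 cases (median 0.51, adjusted p = 1.22e-05, and adjusted p = 0.305 with an estimated correlation), with 0 members passing alone.

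Cell cycle genes stood lower with A2V in 30 of 30 cases (median -0.65, adjusted p = 5.33e-14, and adjusted p = 0.305 with an estimated correlation), as Ccnb2, a cyclin of mitotic entry, did at 16.1 ± 4.46 and 5.77 ± 2.24 RPKM (n = 4 each). Ccnb2 was the 1 member passing when adjusted over the list alone, against 0 over all genes. That count was 0 without A2V replicates 1, 2 or 3 or IgG replicates 1, 3 or 4, and 3 without IgG replicate 2. Genes of tip cells and the VEGF response were lower in 22 of 24 cases (median -0.32, adjusted p = 0.000106, and adjusted p = 0.305 with an estimated correlation), with 0 members passing alone. Among these, Nid2, a basement membrane protein, was at 119 ± 59.5 and 53.4 ± 18.1 RPKM. The receptors of the blocked ligands did not pass: Kdr stood at 178 ± 20.7 and 178 ± 34.4 RPKM, Flt1 at 89.3 ± 13.6 and 77.7 ± 17.2, and Tek at 100 ± 25.1 and 96.7 ± 20.6. Angpt2 itself was at 380 ± 132 and 357 ± 53.7.

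By gene, 0 of 13759 passed with limma for A2V against IgG, 552 had an unadjusted p under 0.05, and the smallest adjusted p was 0.263. Without IgG replicate 1, 1 gene passed. The function lists for MHC class I, type I interferon and T cell chemokines passed with all libraries (adjusted p = 0.00282, 0.00488 and 0.000438, and adjusted p = 0.522, 0.583 and 0.459 with an estimated correlation). The MHC class I call ended without IgG replicate 3 (adjusted p = 0.206), the chemokine call without A2V replicate 2 (0.0566), and the type I interferon call without A2V replicate 2 (0.0791) or IgG replicate 3 (0.263).

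Anti-CD40 alone was compared with IgG to show the response of vessels to CD40 activation without A2V. Type I interferon genes were lower in 26 of 27 cases in endothelial cells, by a median of -0.21 (adjusted p = 1.73e-05, and adjusted p = 0.522 with an estimated correlation), and this call ended without anti-CD40 replicate 2 (adjusted p = 0.263). Each of the 6 lists called here lost its call in at least 1 such fit. Cd40 itself was at 19.5 ± 5.19 RPKM with IgG and 26.4 ± 9.42 with anti-CD40 (n = 4 each) and did not pass. Fibroblast markers were higher in 9 of 9 cases (median 1.09, adjusted p = 2.96e-08, and adjusted p = 0.792 with an estimated correlation). By gene, limma called 0 of 13759, with 165 at an unadjusted p under 0.05.

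The combination against IgG gave the joint response of tumour vessels. Ubd, a ubiquitin-like gene, rose from 125 ± 79.3 RPKM (SD, n = 4) to 691 ± 181 (n = 3). The log2 difference was 2.59 ± 0.36 (adjusted p = 0.0128), and A2V alone gave 348 to 531 RPKM. Interferon gamma genes were higher in 26 of 28 cases (median 1.05): 21 rose when adjusted over the list alone, 0 rose over all genes, and 7 did not pass. Cxcl10 stood at 57.2 ± 31.2 and 168 ± 46 RPKM, Gbp5 at 13.2 ± 3.4 and 37.9 ± 18.7, Irgm2 at 37.1 ± 9.51 and 80.6 ± 18.9, and Cd274 at 12.9 ± 3.47 and 35.7 ± 15.6. The list passed at adjusted p = 9.18e-24, and adjusted p = 0.098 with an estimated correlation, and its count of 21 was 13 without combination replicate 2. Dissociation-stress markers were again higher in 14 of 14 cases (median 0.82, adjusted p = 1.21e-05, and adjusted p = 0.792 with an estimated correlation). Mitochondrial genes made up 5.8% to 10.1% of the summed RPKM in these combination libraries and 4.1% to 7.8% with IgG, 11225 to 12265 genes lay at the floor against 9822 to 11766, and the combination libraries correlated across genes with r of 0.815 to 0.871.

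Genes of MHC class II presentation were higher with the combination in 10 of 11 cases (median 1.01, adjusted p = 9.05e-06, and adjusted p = 0.435 with an estimated correlation). Ciita, the master regulator of class II genes, H2-DMa, H2-DMb1 and H2-DMb2 rose when adjusted over the list alone, against 0 over all genes, and this count of 4 was 0 without combination replicates 2 or 3 or IgG replicates 2 or 3. Class I genes were higher in 20 of 21 cases (median 0.47, adjusted p = 1.56e-06, and adjusted p = 0.305 with an estimated correlation), with 0 passing alone, 1 without combination replicate 1 and 3 without IgG replicate 1. Tip cell genes were lower in 20 of 24 cases (median -0.53, adjusted p = 1.97e-05, and adjusted p = 0.305 with an estimated correlation). Esm1, Cxcr4, Nid2, Ednrb and Lama4 fell when adjusted over the list alone, against 0 over all genes. That count of 5 was 1 without combination replicate 1 and 0 without combination replicate 3 or IgG replicates 3 or 4. Ednrb, an endothelin receptor, was at 257 ± 121 RPKM with IgG and 100 ± 38.3 with the combination, and the chemokine receptor Cxcr4 at 43.9 ± 8.48 and 21.5 ± 5.89. Cell cycle genes were lower in 27 of 30 cases (median -0.56, adjusted p = 6.02e-06, and adjusted p = 0.476 with an estimated correlation), and this call ended without combination replicate 3 (adjusted p = 0.118).

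By gene, limma called 4 of 13759 for the combination against IgG, with 1327 at an unadjusted p under 0.05. Besides Ubd, Cmc4 (ENSMUSG00000090110) rose (log2 difference 2 ± 0.28, adjusted p = 0.0128), and Fkbp14, a chaperone of the endoplasmic reticulum, and A130010J15Rik fell (-1.96 ± 0.27, adjusted p = 0.0128, and -1.66 ± 0.25, adjusted p = 0.0214). These 3 were chosen after their values were seen. The count of 4 was 0 without IgG replicates 2 or 4, 7 without IgG replicate 3, 10 without IgG replicate 1, 21 without combination replicate 3 and 29 without combination replicate 2. Ubd and Fkbp14 each missed the threshold without IgG replicate 2 (adjusted p = 0.0604) or IgG replicate 4 (0.0562), and Fkbp14 also without combination replicate 1 (0.0634).

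**Figure D2:**
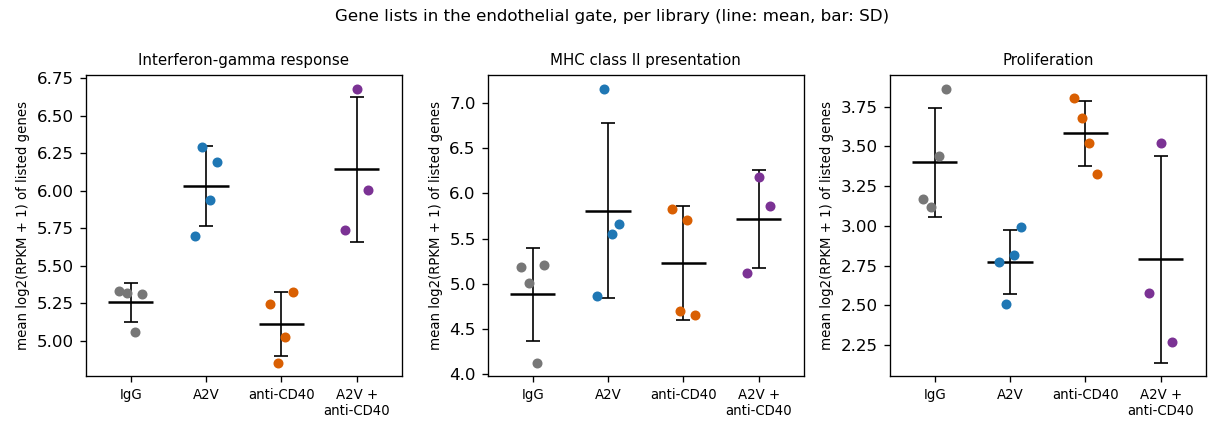
Mean log2(RPKM + 1) of the interferon gamma, MHC class II and proliferation lists in each endothelial library, by treatment; each point is 1 library. Interferon gamma levels lie between 5.05 and 5.33 with IgG, 5.70 and 6.29 with A2V, 4.85 and 5.33 with anti-CD40, and 5.74 and 6.68 with the combination.

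Set against anti-CD40 alone, the combination showed what A2V added in vessels. Ubd rose from 67.8 ± 22.9 RPKM (SD, n = 4) to 691 ± 181 (n = 3), a log2 difference of 3.35 ± 0.36 (adjusted p = 0.00108). Interferon gamma genes were higher in 26 of 28 cases (median 1.15, adjusted p = 1.68e-28, and adjusted p = 0.0786 with an estimated correlation), with 22 rising when adjusted over the list alone and 0 over all genes. Gbp5 was at 9.52 ± 2.87 and 37.9 ± 18.7 RPKM, and Cxcl9, which attracts T cells, at 78.8 ± 26.9 and 213 ± 88. Class I genes were higher in 19 of 21 cases (median 0.43, adjusted p = 1.5e-05, and adjusted p = 0.305 with an estimated correlation). Stress markers were higher in 14 of 14 cases (median 0.83, adjusted p = 1.62e-05, and adjusted p = 0.792 with an estimated correlation).

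Lower with the combination than with anti-CD40 alone were cell cycle genes in 29 of 30 cases (median -0.77, adjusted p = 2.09e-09, and adjusted p = 0.305 with an estimated correlation) and tip cell genes in 20 of 24 (median -0.55, adjusted p = 6.91e-05, and adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, Aurkb, Kif23 and Mcm6 fell among the former and Esm1, Cxcr4, Nid2, Unc5b, Ednrb and Lama4 among the latter, against 0 over all genes in either list. Esm1, a marker of tip cells, was at 349 ± 116 RPKM with anti-CD40 and 162 ± 46.9 with the combination. The cell cycle count of 3 was 0 without combination replicates 1 or 3 or anti-CD40 replicate 1, 1 without anti-CD40 replicate 3 and 22 without combination replicate 2, and the tip cell count of 6 was 1 without combination replicates 1 or 3 or anti-CD40 replicates 2 or 4. Genes of quiescent vessels were higher (17 of 23, median 0.13, mean 0.37, adjusted p = 0.0061, and adjusted p = 0.522 with an estimated correlation), but not without combination replicate 3 (adjusted p = 0.261). By gene, 2 of 13759 passed with limma (Ubd and Fkbp14, with a log2 difference of -1.9 for the latter, chosen after its value was seen), and 1355 had an unadjusted p under 0.05. The count of 2 was 15 without combination replicate 2, 32 without combination replicate 3 and 1 without anti-CD40 replicate 1. Fkbp14 missed the threshold without combination replicate 1 (adjusted p = 0.0835) or anti-CD40 replicates 1, 2 or 4 (0.0578, 0.0673 and 0.0692).

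Set against A2V alone, the combination showed what anti-CD40 added in endothelial cells. Class I genes were higher in 19 of 21 cases (median 0.22, adjusted p = 0.00365, and adjusted p = 0.522 with an estimated correlation), and interferon gamma genes did not pass (adjusted p = 0.0987). Limma called 6 of 13759 genes, with 903 at an unadjusted p under 0.05: Cmc4, C230066G23Rik and the imprinted RNA H19 rose, and Fkbp14, A130010J15Rik and Gm14508 fell. H19 and Fkbp14, chosen after their values were seen, differed by 2.37 ± 0.39 and -1.86 ± 0.27 on the log2 scale and each passed in 1 of 7 fits that left out 1 library. The count of 6 was 2 without A2V replicates 1, 2 or 4, 0 without A2V replicate 3, 1 without combination replicate 1 and 10 without combination replicate 3. The interaction called 0 genes with limma, with 434 at an unadjusted p under 0.05, and 1 gene passed without IgG replicate 1. No interaction call of a function list held in all fits that left out 1 library.

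In macrophages, A2V was compared with IgG to show what blocking the angiogenic ligands changed in the tumour's main phagocytes. Inflammatory macrophage genes were higher in 14 of 17 cases (median 0.39, adjusted p = 1.3e-15), and the call held with an estimated correlation (adjusted p = 0.00856). Irg1, which makes the antimicrobial metabolite itaconate, rose when adjusted over the list alone, from 3.45 ± 1.2 RPKM (SD, n = 4) to 7.24 ± 0.725, against 0 members over all genes. That count of 1 was 0 without A2V replicates 1, 3 or 4 or IgG replicates 1, 3 or 4, 2 without A2V replicate 2 and 4 without IgG replicate 2. Il1b, an inflammatory cytokine, stood at 297 ± 81.3 and 511 ± 141. Costimulation genes were higher in 11 of 13 cases (median 0.22, adjusted p = 3.58e-07), and this call also held with an estimated correlation (adjusted p = 0.0191), with 0 members passing alone.

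Interferon gamma genes in macrophages were higher with A2V in 25 of 27 cases (median 0.38, adjusted p = 6.29e-20, and adjusted p = 0.051 with an estimated correlation), NF-kB targets in 17 of 20 (median 0.35, adjusted p = 1.85e-13, and adjusted p = 0.0871 with an estimated correlation) and MHC class II genes in 11 of 12 (median 0.19, adjusted p = 3.66e-05, and adjusted p = 0.0961 with an estimated correlation). T cell chemokines were higher in 8 of 10 (median 0.28, adjusted p = 1.47e-05, and adjusted p = 0.197 with an estimated correlation). Cell cycle genes were lower in 29 of 30 (median -0.36, adjusted p = 8.49e-09, and adjusted p = 0.254 with an estimated correlation). None of these 5 lists had a member passing alone. Gbp2, a guanylate-binding protein, was at 176 ± 48.4 and 254 ± 33 RPKM. Endothelial markers (median 0.29, adjusted p = 0.00189) and stress markers (median 0.27, adjusted p = 2.99e-05) were higher too, both at adjusted p = 0.187 with an estimated correlation. By gene, limma called 0 of 11445, with 156 at an unadjusted p under 0.05.

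Anti-CD40 was compared with IgG in macrophages, which carry CD40. Il12b, a subunit of the interleukins 12 and 23, rose from 4.92 ± 2.1 RPKM (SD, n = 4) to 48.6 ± 17.6, a log2 difference of 3.05 ± 0.38 (adjusted p = 0.0059), and passed in each of the 8 fits that left out 1 library, though not with a replicate block taken from the order of library numbers (adjusted p = 0.0527). Ccl24, an eosinophil-attracting chemokine of alternatively activated macrophages, fell from 78.1 ± 35.9 to 2.5 ± 1.37 RPKM (-4.41 ± 0.63, adjusted p = 0.0191). Alternative macrophage genes were lower on balance (11 of 20 lower, median -0.35, adjusted p = 0.000427, and adjusted p = 0.197 with an estimated correlation). Adjusted over the list alone, Arg1, Ccl24, Pdcd1lg2 and Cd36 fell, against 1 fall over all genes, while Ccl22, a chemokine that dendritic cells also make, rose from 3.29 ± 1.01 to 22.6 ± 12.6 RPKM. The ligand of PD-1 encoded by Pdcd1lg2 was at 22.6 ± 7.36 RPKM with IgG and 4.65 ± 2.85 with anti-CD40. The count of 4 falls was 2 without IgG replicate 1 or anti-CD40 replicates 1 or 3.

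Inflammatory and costimulation genes were higher with anti-CD40 in 11 of 17 and 7 of 13 cases (medians 0.13 and 0.09, adjusted p = 7.04e-05 and 0.000702, and adjusted p = 0.1 and 0.091 with an estimated correlation). Il12b, Il1a and Cd80 rose in the first list and Il12b, Cd80 and Ccr7 in the second when adjusted over the list alone, against 1 each over all genes. Cd80, a ligand of CD28 on T cells, was at 2.84 ± 0.581 and 6.66 ± 1.26 RPKM, and Ccr7, which guides cells to lymph nodes, at 0.868 ± 0.618 and 7.54 ± 4.42. NF-kB targets were higher in 17 of 20 cases (median 0.36, adjusted p = 3.93e-06, and adjusted p = 0.21 with an estimated correlation). Endothelial markers were higher in 6 of 7 cases (median 0.48, adjusted p = 1.46e-05, and adjusted p = 0.187 with an estimated correlation). Limma called 3 of 11445 genes, with 269 at an unadjusted p under 0.05, and the other gene was Chst2 (1.49 ± 0.22, adjusted p = 0.0235), chosen after its value was seen and past the threshold in 1 of 8 such fits. The count was 1 without IgG replicates 1, 2 or 4 or anti-CD40 replicates 2 or 3, and Ccl24 missed the threshold without IgG replicates 1, 2 or 4 (adjusted p = 0.105, 0.0703 and 0.118) or anti-CD40 replicates 1, 2 or 3 (0.055, 0.0888 and 0.119).

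The combination against IgG gave the joint response of macrophages. Cxcl13, a chemokine that attracts B cells, rose from 22.2 ± 14.5 RPKM (SD, n = 4) to 672 ± 500, a log2 difference of 4.83 ± 0.48 (adjusted p = 0.000328), with 1388 in combination replicate 1 and 266 to 626 in the others. Pla2g2d, a secreted phospholipase, rose from 10.7 ± 3.21 to 193 ± 191 RPKM (3.62 ± 0.47, adjusted p = 0.00225), with 475 in that library and 58.8 to 140 in the others. Il12b rose from 4.92 ± 2.1 to 44.4 ± 27 (2.84 ± 0.38, adjusted p = 0.00225). Nr1h3, which encodes the oxysterol receptor LXR alpha, rose from 15 ± 2.91 to 48.9 ± 17.5 RPKM, and Irg1 from 3.45 ± 1.2 to 16 ± 2.35. These 5 genes and Spic, a transcription factor of red pulp macrophages at 4.51 ± 0.551 and 14.7 ± 6.84 RPKM that was chosen after its values were seen, passed in each of the 8 fits that left out 1 library.

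In all, limma called 31 of 11445 macrophage genes for the combination against IgG, 27 up and 4 down, with 1144 at an unadjusted p under 0.05. The acute-phase gene Saa3 rose from 4.3 ± 1.99 to 30.9 ± 16.7 RPKM, but missed the threshold without IgG replicate 4 (adjusted p = 0.0515) or combination replicate 1 (0.0543). Serpinb9, a granzyme B inhibitor, rose from 7.22 ± 1.07 to 14.2 ± 1.83, and missed it without IgG replicate 4 (0.0902) or combination replicates 2 or 3 (0.0652 and 0.051). The named genes Ly6i, Mcemp1, Tnfaip2 and Il2rg rose and the interleukin 7 receptor Il7r fell, but each passed in only 2 or 3 of 8 fits that left out 1 library. The count of 31 was 16 without IgG replicates 1 or 3 or combination replicate 2, 11 without IgG replicate 4, 13 without combination replicate 1 and 96 without combination replicate 4. Mitochondrial genes made up 3.5% to 8.1% of the summed RPKM in these combination libraries and 2.6% to 4.8% with IgG, and 10927 to 12418 genes lay at the floor against 9549 to 11136.

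**Figure D3:**
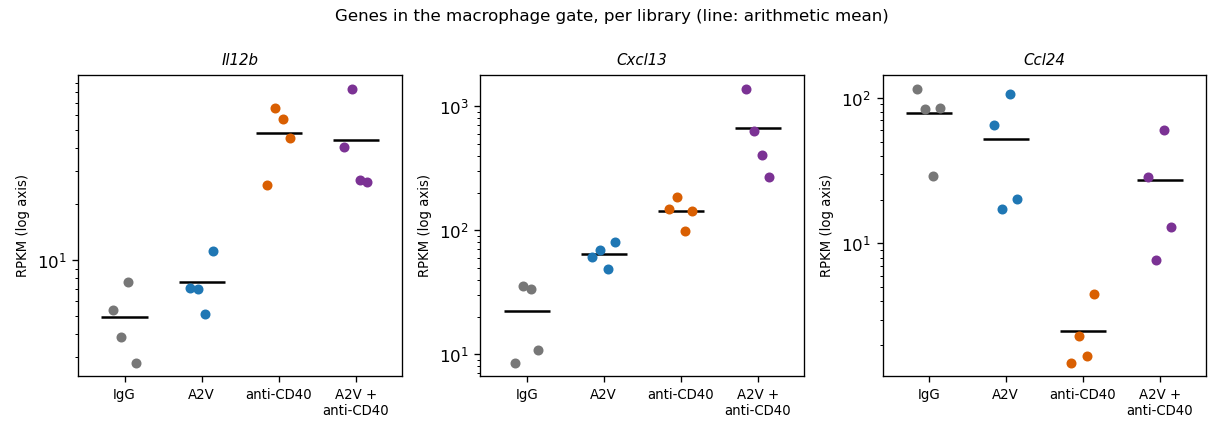
RPKM of Il12b, Cxcl13 and Ccl24 in each macrophage library on a logarithmic axis, by treatment; each point is 1 library. Mean Il12b is 4.92 with IgG, 7.6 with A2V, 48.6 with anti-CD40 and 44.4 with the combination, and mean Ccl24 is 78.1, 52.1, 2.5 and 27.3.

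Inflammatory macrophage genes were higher with the combination in 15 of 17 cases (median 0.65, adjusted p = 9.02e-10, and adjusted p = 0.0191 with an estimated correlation), and 6 rose when adjusted over the list alone, against 2 over all genes. Costimulation genes were higher in 8 of 13 cases (median 0.61, adjusted p = 3.6e-06, and adjusted p = 0.0191 with an estimated correlation), and 7 rose when adjusted over the list alone, against 1 over all genes: Cd40, Cd80, Tnfsf9, Ccr7, Il12b, Il15 and Il15ra. Cd40 was at 35 ± 2.12 RPKM with IgG and 54 ± 3.73 with the combination (n = 4 each). Perivascular macrophage genes were higher in 12 of 13 cases (median 0.88, adjusted p = 8.9e-06, and adjusted p = 0.197 with an estimated correlation). Cxcr4, Hmox1, Folr2, Timd4, Pf4 and Ccl8 rose when adjusted over the list alone, against 0 over all genes. That count of 6 was 1 without combination replicate 1, 3 without combination replicate 2 or IgG replicate 4, 4 without IgG replicate 2 and 0 without IgG replicate 3. Pf4, a chemokine also stored in platelets, stood at 94.3 ± 33.5 and 786 ± 1070 RPKM, and the folate receptor Folr2 at 40.1 ± 16.6 and 147 ± 135. Combination replicate 1 held 2390 RPKM of Pf4 against 209 to 308 in the others, and 348 of Folr2 against 57.1 to 110. In the same groups the mean log2 level of platelet markers was 1.44 ± 0.1 with IgG and 2.13 ± 0.55 with the combination, and that of plasma cell markers 1.84 ± 0.9 and 3.6 ± 1.44, neither of them tested as a list in macrophages.

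Further lists higher with the combination were interferon gamma genes (26 of 27, median 0.52, adjusted p = 8.09e-12, and adjusted p = 0.112 with an estimated correlation), NF-kB targets (18 of 20, median 0.68, adjusted p = 1.1e-10, and adjusted p = 0.1 with an estimated correlation), MHC class I genes (18 of 21, median 0.28, adjusted p = 0.000236, and adjusted p = 0.198 with an estimated correlation) and T cell chemokines (7 of 10, median 0.69, adjusted p = 2.02e-05, and adjusted p = 0.197 with an estimated correlation). Traf1, an adaptor of TNF receptors, was at 1.64 ± 0.872 RPKM with IgG and 7.86 ± 5.13 with the combination, and Ccl22 at 3.29 ± 1.01 and 30.9 ± 28.8, with 71.1 in combination replicate 1 and 6.02 to 31.4 in the others. Cell cycle genes were lower in 28 of 30 cases (median -0.43, adjusted p = 2.17e-05, and adjusted p = 0.391 with an estimated correlation). Endothelial markers (median 0.7, adjusted p = 0.00189, and adjusted p = 0.187 with an estimated correlation) and stress markers (median 0.18, adjusted p = 0.00732, and adjusted p = 0.437 with an estimated correlation) were higher in the same libraries.

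Against A2V alone, the combination raised Cxcl13 from 64.6 ± 13.1 RPKM (n = 4) to 672 ± 500 (log2 difference 3.1 ± 0.48, adjusted p = 0.0367), Pla2g2d from 19.9 ± 3.31 to 193 ± 191 (2.76 ± 0.47, adjusted p = 0.0476) and Il12b from 7.6 ± 2.55 to 44.4 ± 27 (2.28 ± 0.38, adjusted p = 0.04) in macrophages. Perivascular macrophage genes were higher in 12 of 13 cases (median 0.75, adjusted p = 0.000331, and adjusted p = 0.26 with an estimated correlation). Hmox1, Folr2, Pf4 and Gas6 rose when adjusted over the list alone, against 0 over all genes, and this count of 4 was 0 without A2V replicate 4 and 2 without combination replicate 1. The remaining 6 calls of lists each ended in at least 1 fit that left out a library. Limma called 6 of 11445 genes, all of them up, with 984 at an unadjusted p under 0.05, and the count was 0 without A2V replicates 1, 2 or 4 or combination replicate 1, 1 without A2V replicate 3, 2 without combination replicate 2 and 58 without combination replicate 4. Cxcl13 and Il12b each passed in 2 of 8 such fits and Pla2g2d in 1 of 8.

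Against anti-CD40 alone, alternative macrophage genes were higher with the combination in 17 of 20 cases (median 0.68, adjusted p = 2.02e-06, and adjusted p = 0.0981 with an estimated correlation). Arg1, Il10, Ccl24, Pdcd1lg2 and Ccl8 rose when adjusted over the list alone, against 0 over all genes, and the count of 5 was 9 without anti-CD40 replicate 4. The arginine-degrading enzyme Arg1 was at 37.7 ± 18.1 RPKM with anti-CD40 and 287 ± 179 with the combination, Ccl24 at 2.5 ± 1.37 and 27.3 ± 23.6, and Pdcd1lg2 at 4.65 ± 2.85 and 20 ± 14.7. Interferon gamma genes were higher in 26 of 27 cases (median 0.51, adjusted p = 3.24e-10, and adjusted p = 0.155 with an estimated correlation), as Cxcl11, a T cell chemokine, was at 7.76 ± 2.22 and 19.2 ± 3.33 RPKM. T cell chemokines (median 0.46, adjusted p = 0.000307, and adjusted p = 0.254 with an estimated correlation), inflammatory genes (median 0.22, adjusted p = 0.00179, and adjusted p = 0.197 with an estimated correlation) and perivascular genes (median 0.64, adjusted p = 0.000596, and adjusted p = 0.289 with an estimated correlation) were also higher. Cell cycle genes were lower in 29 of 30 cases (median -0.59, adjusted p = 5.57e-08, and adjusted p = 0.26 with an estimated correlation).

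By gene, limma called 6 of 11445 in macrophages between the combination and anti-CD40, 5 up and 1 down, with 1154 at an unadjusted p under 0.05. Qpct, which cyclises N-terminal glutamine, fell from 40 ± 8.41 to 11.3 ± 3.44 RPKM (-1.76 ± 0.24, adjusted p = 0.0107), and the tetraspanin Tspan32 rose from 15.6 ± 3.41 to 39.2 ± 9.89 (1.27 ± 0.21, adjusted p = 0.0429). Ubd rose from 0.725 ± 0.76 to 9.86 ± 4.25 RPKM (2.65 ± 0.36, adjusted p = 0.0107) and was chosen after its value was seen. Cd40 was at 31.3 ± 3.58 and 54 ± 3.73 RPKM (0.77 ± 0.13) and did not pass, at adjusted p = 0.05. The count of 6 was 0 without combination replicate 1, 48 without combination replicate 4, 1 without anti-CD40 replicate 1 and 3 without anti-CD40 replicate 3. Qpct missed the threshold without combination replicate 1 (adjusted p = 0.0569), Ubd without that library (0.0569) or anti-CD40 replicate 1 (0.0565), and Tspan32 passed in 2 of 8 such fits.

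The interaction asked whether the effect of A2V on macrophages differed with anti-CD40. Alternative macrophage genes had a positive interaction in 16 of 20 cases (median 0.69, adjusted p = 0.000913, and adjusted p = 0.21 with an estimated correlation), with Ccl24 passing when adjusted over the list alone, against 0 genes over all genes. The list call held in 16 of 16 fits that left out 1 library, while the count of 1 was 0 in 9 of them (without A2V replicates 2 or 4, combination replicates 1 or 3, IgG replicates 1, 2 or 4, or anti-CD40 replicates 1 or 3) and 2 without combination replicate 4 or IgG replicate 3. Tumour epithelial markers had a positive interaction as well, in 9 of 9 cases (median 1.46, adjusted p = 0.00189, and adjusted p = 0.524 with an estimated correlation). Limma called 0 of 11445 genes, with 450 at an unadjusted p under 0.05.

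In CD8 T cells, A2V was compared with IgG to ask whether blocking the angiogenic ligands changed killer T cells. T cell activation genes were higher in 15 of 16 cases (median 0.25, adjusted p = 1.78e-05, and adjusted p = 0.13 with an estimated correlation). Cd69, an early activation antigen, was at 160 ± 29.2 RPKM (SD, n = 4) with IgG and 225 ± 70.2 with A2V, and Il2ra, the alpha chain of the interleukin 2 receptor, at 26.8 ± 6.12 and 41.9 ± 19.1. Markers of CD4 T cells stood at a mean log2 level of 2.58 ± 0.28 with IgG and 3.23 ± 0.35 with A2V in these CD8 gate libraries, and regulatory T cell genes, a list that also holds Il2ra, at 4.15 ± 0.12 and 4.48 ± 0.25, neither of them tested as a list in this gate. Inhibitory receptor genes were higher in 16 of 21 cases (median 0.12, adjusted p = 0.000343, and adjusted p = 0.331 with an estimated correlation). Neither list had a member passing alone. By gene, 0 of 13193 passed with limma, and 216 had an unadjusted p under 0.05.

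With anti-CD40 alone, type I interferon genes in CD8 T cells were lower than with IgG in 25 of 27 cases (median -0.47, adjusted p = 1.1e-10, and adjusted p = 0.331 with an estimated correlation). The antiviral gene Mx2 was at 7.65 ± 0.502 and 3.64 ± 1.47 RPKM (n = 4 each), Oasl2 at 14 ± 7.48 and 4.94 ± 2.29, and Bst2, which tethers virions, at 136 ± 34 and 73.1 ± 36.3. Cell cycle genes were higher in 30 of 30 cases (median 0.37, adjusted p = 8.86e-07, and adjusted p = 0.464 with an estimated correlation). Neither list had a member passing alone, and 2 type I interferon genes passed without anti-CD40 replicate 3. Plasmacytoid dendritic cell markers were lower in the same libraries (5 of 6, median -0.99, adjusted p = 0.00351, and adjusted p = 0.803 with an estimated correlation), though not past the threshold without anti-CD40 replicate 1 (adjusted p = 0.0967). Of 13193 genes, limma called 0, with 260 at an unadjusted p under 0.05.

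The combination against IgG showed higher Havcr2, which encodes the inhibitory receptor TIM-3, at 68.9 ± 16.2 RPKM (SD, n = 4) against 26.9 ± 5.43, and higher Prf1, the pore-forming perforin, at 370 ± 118 against 165 ± 48.1. Neither passed over all genes (log2 differences 1.31 ± 0.2 and 1.16 ± 0.27, adjusted p = 0.0682 and 0.315), and Havcr2 passed without combination replicate 2 (adjusted p = 0.023). Adjusted over the inhibitory receptor list alone, Havcr2 and Entpd1, which degrades extracellular ATP, were among 3 members that rose and Litaf and Cd200r4 among 3 that fell, against 0 over all genes, and the list itself did not pass (adjusted p = 0.496). These counts of 3 and 3 were 2 and 0 without combination replicate 3, 7 and 3 without combination replicate 4, and 3 and 1 without IgG replicate 4. In the cytotoxic list Prf1 rose when adjusted over the list alone, though not without combination replicate 3, and the list's median of 0.1, mean of -0.01 and downward test (adjusted p = 0.624) differed in sign. Targets of NF-kB were higher in 19 of 20 cases (median 0.49, adjusted p = 0.00208, and adjusted p = 0.464 with an estimated correlation) and type I interferon genes lower in 22 of 27 (median -0.38, adjusted p = 8.86e-07, and adjusted p = 0.464 with an estimated correlation). The median of all genes differed by 0.139 in this contrast, by 0.16 against A2V and by 0.108 in the interaction. Limma called 0 of 13193 genes, with 1138 at an unadjusted p under 0.05, and 2 without combination replicate 2.

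Set against A2V alone in CD8 T cells, the combination had higher cell cycle genes in 29 of 30 cases (median 0.64, adjusted p = 3.02e-06, and adjusted p = 0.469 with an estimated correlation). Limma called 0 of 13193 genes in this contrast, with 1020 at an unadjusted p under 0.05.

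Set against anti-CD40 alone, cytotoxic genes of CD8 T cells did not pass as a list (median 0.16, adjusted p = 0.185), while Prf1, Ifng, Ccl3, Ccl4 and Zeb2 rose when adjusted over the list alone, against 0 over all genes. Prf1 was at 124 ± 24.3 RPKM with anti-CD40 and 370 ± 118 with the combination (n = 4 each), Ifng, the gene of interferon gamma, at 162 ± 32.8 and 294 ± 33.3, and the chemokine Ccl3 at 142 ± 68.7 and 352 ± 117. The count of 5 was 2 without combination replicates 1 or 3 or anti-CD40 replicates 2 or 3, and 3 without combination replicate 2 or anti-CD40 replicate 1. The list passed without combination replicate 3 (adjusted p = 0.0113) or anti-CD40 replicate 4 (0.00111). Targets of NF-kB were higher in 18 of 20 cases (median 0.32, adjusted p = 0.00361, and adjusted p = 0.464 with an estimated correlation). Across 13193 genes limma called 0, and 453 had an unadjusted p under 0.05. In the interaction, inhibitory receptor genes were negative in 13 of 21 cases (median -0.2, adjusted p = 0.000992, and adjusted p = 0.331 with an estimated correlation), and limma called 0 genes, with 286 at an unadjusted p under 0.05.

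In CD4 T cells, A2V against IgG gave small shifts of helper programmes. Th1 genes were higher in 13 of 18 cases (median 0.11, adjusted p = 0.00412), cytotoxic genes in 17 of 22 (median 0.14, adjusted p = 0.00349) and inhibitory receptor genes in 14 of 21 (median 0.15, adjusted p = 0.00425), each at adjusted p = 0.528 with an estimated correlation and with 0 members passing alone. Cell cycle genes were lower in 28 of 30 cases (median -0.29, adjusted p = 0.00125, and adjusted p = 0.643 with an estimated correlation), as the mitotic kinase Aurkb was at 17.2 ± 2.06 and 12.2 ± 1.26 RPKM (SD, n = 4 each). That call ended without A2V replicate 3 (adjusted p = 0.0546) or IgG replicate 2 (0.0691). Red cell genes were lower by a mean log2 difference of -3.3 between these same libraries (exact permutation p = 0.0286, two-sided, the smallest possible), as in the other gates with A2V. No gene of 13562 passed with limma, a count of 0, with 455 at an unadjusted p under 0.05.

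With anti-CD40 alone, regulatory T cell genes in the CD4 gate were lower than with IgG in 19 of 21 cases (median -0.37, adjusted p = 0.000805, and adjusted p = 0.616 with an estimated correlation). Il2ra was at 177 ± 54.2 and 84.9 ± 39.4 RPKM (n = 4 each), Il1rl1, the receptor of interleukin 33, at 31.4 ± 7.64 and 16.3 ± 9.97, and Gpr83 at 5.13 ± 1.58 and 2.46 ± 0.523. These 3 fell when adjusted over the list alone, against 0 over all genes, and the count was 0 without IgG replicates 1 or 2 or anti-CD40 replicates 2 or 3 and 6 without anti-CD40 replicate 4. Macrophage markers were higher in the same libraries in 13 of 13 cases (median 0.81, adjusted p = 4.83e-10, and adjusted p = 0.707 with an estimated correlation), and Lyz2 stood at 4150 ± 1300 RPKM against 861 ± 163. Plasmacytoid dendritic cell markers were lower in 6 of 6 cases (median -0.84, adjusted p = 0.000301, and adjusted p = 0.707 with an estimated correlation), but not past the threshold without anti-CD40 replicate 1 (adjusted p = 0.0558). The median of all genes differed by -0.12 in this contrast, by 0.111 between the combination and anti-CD40, and by 0.202 in the interaction. Among 13562 genes 0 passed with limma, and 935 had an unadjusted p under 0.05.

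**Figure D4:**
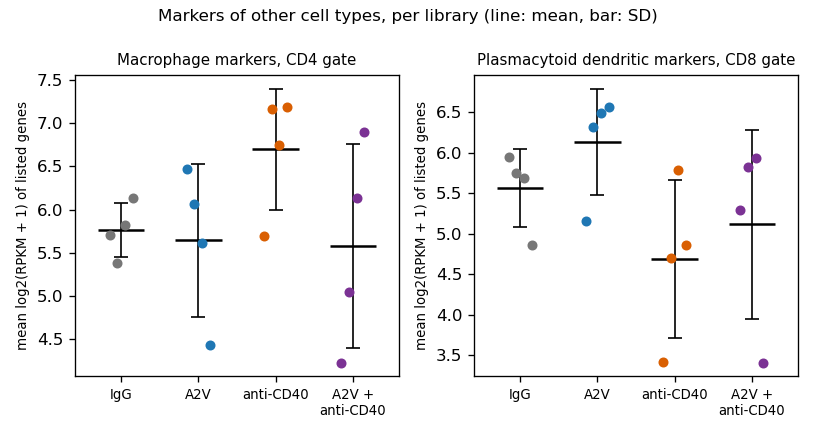
Mean log2(RPKM + 1) of macrophage markers in each CD4 library and of plasmacytoid dendritic cell markers in each CD8 library, by treatment; each point is 1 library. The median macrophage marker in CD4 libraries differs by 0.81 between anti-CD40 and IgG and by -1.13 between the combination and anti-CD40.

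The combination was compared with IgG to show the joint response of helper T cells. Genes of the Th2, Th17 and follicular helper list were higher in 14 of 19 cases (median 0.38, adjusted p = 0.000208, and adjusted p = 0.528 with an estimated correlation). Il17a, the signature cytokine of Th17 cells, was at 2.24 ± 0.874 RPKM (SD, n = 4) with IgG and 16.2 ± 9.58 with the combination. Il1r1 was at 0.7 ± 0.218 and 3.17 ± 1.89, Il23r at 0.725 ± 0.435 and 2.72 ± 1.65, and Il22 at 0.183 ± 0.248 and 4.82 ± 7.02 (15.2 in combination replicate 1), each a receptor or cytokine of Th17 cells. These 4, Il17f and Sh2d1a were among the 7 members that rose when adjusted over the list alone, against 0 over all genes. The count of 7 was 2 without combination replicate 1 or IgG replicate 2, 3 without IgG replicates 1 or 3 and 4 without combination replicate 3. Between 9617 and 10476 genes lay at the floor in the CD4 combination libraries, against 7945 to 9259 with IgG, and mitochondrial genes made up 4.5% to 9.9% of the summed RPKM against 2.5% to 4.5%.

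Targets of NF-kB were higher with the combination in 19 of 20 cases in CD4 T cells (median 0.48, adjusted p = 0.000205, and adjusted p = 0.528 with an estimated correlation), and cell cycle genes lower in 28 of 30 (median -0.33, adjusted p = 0.000205, and adjusted p = 0.617 with an estimated correlation). Stress markers were higher in 12 of 13 cases (median 0.35, adjusted p = 0.00138, and adjusted p = 0.791 with an estimated correlation). Limma called 1 of 13562 genes, with 901 at an unadjusted p under 0.05. That gene, Art2a-ps, a pseudogene of an ADP-ribosyltransferase, rose from 1.47 ± 0.195 to 8.42 ± 3.47 RPKM (1.86 ± 0.25, adjusted p = 0.0228) and was chosen after its value was seen. The count was 0 without any 1 of IgG replicates 1 to 4 or combination replicates 2 to 4, and 4 without combination replicate 1.

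Compared with A2V alone, the combination had lower T cell activation genes in 13 of 16 cases (median -0.15, adjusted p = 0.00415, and adjusted p = 0.528 with an estimated correlation). Plasmacytoid dendritic cell markers were lower in the same libraries (5 of 6, median -0.72, adjusted p = 0.000236, and adjusted p = 0.707 with an estimated correlation). The helper list was higher (median 0.25, adjusted p = 0.0347, and adjusted p = 0.643 with an estimated correlation), but this call ended without A2V replicates 2 or 3 (adjusted p = 0.109 and 0.119) or combination replicates 1 or 2 (0.183 and 0.12). The smallest adjusted p of any gene with limma was 0.773, so 0 of 13562 passed.

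Compared with anti-CD40 alone, genes of naive and memory T cells were higher with the combination in 17 of 18 cases (median 0.37, adjusted p = 0.000805, and adjusted p = 0.528 with an estimated correlation), with 0 members passing alone. The transcription factor Tcf7 was at 59 ± 7.73 RPKM (n = 4) with anti-CD40 and 101 ± 49.1 with the combination, and Klf2, a regulator of T cell egress, at 4.29 ± 1.21 and 7.97 ± 2.7. Macrophage markers were lower in 13 of 13 cases (median -1.13, adjusted p = 4.83e-10, and adjusted p = 0.707 with an estimated correlation). Limma called 4 of 13562 genes, all of them down, with 1259 at an unadjusted p under 0.05: Haao (-2.09 ± 0.32), Olfr110 (-1.53 ± 0.24), Zfp791 (-2.05 ± 0.33) and 1810011H11Rik (-1.34 ± 0.21), each at adjusted p = 0.0385, of which the first 3 were chosen after their values were seen. The count was 2 without anti-CD40 replicate 1, 1 without combination replicate 4 and 0 without any 1 of the other 6 libraries. The interaction called 0 of 13562 genes with limma, with 844 at an unadjusted p under 0.05, and macrophage markers were negative in 13 of 13 cases (median -1.07, adjusted p = 4.93e-07, and adjusted p = 0.791 with an estimated correlation).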

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

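The tests of the scale of the values, the test of a lower T cell share in the CD4 gate, and all comparisons of replicates were chosen after the data were seen.

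The first pattern weighed was the higher level of interferon gamma genes in endothelial cells with A2V, a mean log2 difference of 0.79. With the macrophage marker level as a covariate the difference was 0.75 (95% interval 0.34 to 1.16), which argues against macrophage RNA as the whole cause. After median-of-ratios scaling it was 0.83 (0.35 to 1.3), which argues against the scale of the values. T cell markers fell, so 1.1 (0.66 to 1.53) with a T cell covariate decides nothing. Dissociation-stress markers were higher in the same libraries by a median of 0.79, and a shared effect of cell handling stays open. No biological explanation was tested.

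The second pattern was the higher level of macrophage genes in the CD4 gate with anti-CD40 alone. Of 118 genes over 16 times higher in macrophage than in CD8 gate libraries, 105 were higher (88.98%), with a median log2 difference of 0.79. The interval of 0.64 to 0.85 came from resampling these genes, which are not independent replicates, and does not measure the spread between libraries. Per library, the mean log2 level of macrophage markers was 5.76 ± 0.31 with IgG and 6.7 ± 0.7 with anti-CD40 (SD, n = 4 each). More macrophage RNA in the gate is a candidate explanation. The gate took CD11b-negative cells, a step that would remove macrophages, and of the 13 measured markers 5 are in another list and 12 also reach 1 RPKM in the CD8 gate. A lower T cell share would by itself raise the markers of every other cell type, while plasmacytoid dendritic cell markers differed by -0.84. They were lower in the CD8 gate as well and may have fallen separately. In the CD4 gate tumour epithelial, fibroblast, neutrophil, pericyte and plasma cell markers (2.26 ± 0.38 against 3.07 ± 0.44 with IgG) were lower too. Platelet markers were higher (1.12 ± 0.2 against 0.76 ± 0.14), so a lower T cell share stays open. T cell markers (7.54 ± 0.06 against 7.7 ± 0.25) do not decide either. Whether macrophages were more numerous or more often bound to T cells stays open, and no biological explanation was tested.

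The last pattern was the lower level of type I interferon genes in the CD8 gate with anti-CD40 alone, a mean log2 difference of -0.5. A scale difference would move all genes alike, while the median of all genes tested differed by 0.03 (95% interval -0.17 to 0.23), which argues against the scale of the values. An earlier test, the list after median-of-ratios scaling, gave -0.54 with an interval that includes 0 (-1.16 to 0.07). It did not decide, and between libraries the fall itself was not set apart from 0. With the plasmacytoid dendritic cell marker level as a covariate the list differed by -0.51, with an interval from -1.17 to 0.15 that includes 0 and the unadjusted value, so less RNA of these cells cannot be told apart from a change in the T cells with 4 libraries per group. No biological explanation was tested.

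Whether chance can be excluded was examined by regrouping the libraries of each pair of treatments in all 35 ways, or in 100 drawn ways for the interaction. In macrophages, the real grouping alone, 1 of 35, reached its count of changed genes for the combination against IgG (31, highest other 8) and against A2V (6, highest other 1). In endothelial cells this held against A2V (6, highest other 2) and in CD4 T cells against IgG (1, highest other 0). For list members adjusted over the list alone, the real grouping was again 1 of 35 for endothelial interferon gamma genes with A2V (17, highest other 4) and with the combination against IgG (21, highest other 8) or anti-CD40 (22, highest other 21). The same was found with the combination against IgG for inflammatory (6, highest other 5), costimulation (7, highest other 4) and perivascular genes (6, highest other 3) of macrophages and for helper genes of CD4 T cells (7, highest other 6), and against anti-CD40 for cytotoxic genes of CD8 T cells (5, highest other 2). Among these groupings chance is excluded as far as 1 of 35 allows for each result taken by itself, with no allowance for the number of results regrouped. The margins of 22 over 21, 6 over 5, 7 over 6 and 1 over 0 are a single gene each, and the count of 1 in CD4 T cells was 0 in 7 of the 8 fits that left out 1 library. The groupings took no account of the order of library numbers, and with the replicate block 0 genes passed for the combination against A2V in endothelial cells or macrophages, so those counts stay open.

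Chance could not be excluded for 6 further counts, and list counts not given here were not regrouped. In endothelial cells, 3 of 35 groupings reached the 4 genes of the combination against IgG (highest other 129), 2 of 35 the 2 genes against anti-CD40 (highest other 2), and 2 of 35 the 5 tip cell genes (highest other 5). In macrophages, 3 of 35 reached the 3 genes of anti-CD40 against IgG (highest other 2233) and 2 of 35 the 6 genes of the combination against anti-CD40 (highest other 445). The grouping with 2233 genes set the library sets 1 and 2, taken from the order of library numbers, against sets 3 and 4, each side holding 2 libraries of either treatment, and with the replicate block 0 genes passed in that contrast. In CD4 T cells, 2 of 35 reached the 4 genes of the combination against anti-CD40 (highest other 161). Any grouping reaches a count of 0, 35 of 35 or 100 of 100 for the interaction, which decides nothing. Groupings with 2233, 445, 161 and 129 genes, and 4498 and 524 in the macrophage and endothelial interactions, point to sample structure other than treatment. In macrophages the first principal component held 35.99% of the variance. It was -56 in IgG replicate 2 (highest sum of RPKM, 670132) and 47.7 in anti-CD40 replicate 1 (lowest, 471120), an untested link.

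Among groups of replicates, 28 of 375 tested (7.5%) held 1 library far from the others, and chance flags about 1 in 20 groups. In endothelial cells with IgG, replicate 1 held 104 RPKM of Cxcl10 against 41.2 to 42.3 in the other replicates, 100 of Bgn against 60.3 to 64.8, and 243 of Ubd against 77.4 to 95. With A2V, replicate 2 held 296 RPKM of H2-DMa against 122 to 147, and replicate 4 held 1.34 of H19 against 0.06 to 0.11. The mean log2 level of interferon gamma genes in IgG replicate 3 was 5.05 against 5.31 to 5.33.

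In macrophages with the combination, replicate 1 held 2390 RPKM of Pf4 against 209 to 308 and 24.9 of Spic against 10.5 to 12.4, and replicate 2 held 74.9 of Nr1h3 against 37.8 to 43.7. With IgG, replicate 2 held 144 RPKM of Pf4 against 72 to 84 and replicate 3 held 2.94 of Traf1 against 1.04 to 1.3. Mean log2 levels stood apart for costimulation genes in A2V replicate 4 (3.04 against 2.70 to 2.74), MHC class II genes in IgG replicate 1 (9.07 against 9.27 to 9.31) and inflammatory genes in anti-CD40 replicate 1 (3.81 against 4.05 to 4.07). The sum of RPKM was 584951 in A2V replicate 1 against 500165 to 512146, and 670132 in IgG replicate 2 against 485662 to 496075.

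In CD8 T cells with anti-CD40, replicate 4 held 245 RPKM of Ccl3 against 104 to 114, mean log2 levels of 5.69 for cytotoxic genes against 5.09 to 5.16 and of 5.54 for inhibitory receptor genes against 5.89 to 5.91, and a sum of RPKM of 658910 against 490863 to 503575. Replicate 1 of that group held 39.9 RPKM of Havcr2 against 27.7 to 29, and combination replicate 2 held 344 of Ifng against 273 to 280.

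In CD4 T cells with the combination, replicate 1 held 15.2 RPKM of Il22 against 0.38 to 2.72 and 175 of Tcf7 against 73.2 to 84, and replicate 4 held 1.55 of Zfp791 against 0.03 to 0.15. With IgG, replicate 1 held 7.48 of Gpr83 against 4.14 to 4.63 and replicate 4 held 0.55 of Il22 against 0.03 to 0.11. Il23r was at 0.19 RPKM in A2V replicate 3 against 1.05 to 1.21.

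The effect of A2V differed with and without anti-CD40, by the interaction at the preset correlation, for 9 lists. In macrophages the median difference was 0.69 for alternative genes, 0.77 for perivascular genes, 0.30 for hypoxia genes and -0.20 for cell cycle genes. It was 0.27 for interferon gamma genes and 0.14 for MHC class I genes in endothelial cells. In CD8 T cells it was -0.20 for inhibitory receptor genes and -0.08 for activation genes, and in CD4 T cells -0.24 for cytotoxic genes. None of these 9 passed with an estimated correlation, and those for alternative macrophage genes and CD8 inhibitory receptor genes held in each of the 16 fits that left out 1 library.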

How the results depend on the processing

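The fits without the library that stood apart in each cell type and those with the macrophage marker level as a covariate were chosen after the data were seen. The planned count-based normalisations could not be run on RPKM, and median-of-ratios scaling took their place. The depth and the 0.01 rounding of the values limit genes near the floor. No call reversed direction. List calls totalled 129 at the preset correlation, 4 with an estimated one, 120 with scaling and 130 with the replicate block. They were 139 without the library that stood apart and 138 with the macrophage covariate. For each count that moved, the cause was not tested, except that the fits on the 2 groups alone rest on fewer libraries.

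In endothelial cells the combination against IgG gave 8 genes with a pseudocount of 0.1, 1 with the replicate block and 0 with only the 2 groups. Against A2V it gave 2 without the expression filter, 0 with the replicate block, 0 with only the 2 groups and 1 without the library that stood apart. Against anti-CD40 it gave 1 with scaling, 8 with the replicate block, 11 with a pseudocount of 0.1 and 4 with the macrophage covariate. Anti-CD40 against IgG gave 1 with only the 2 groups, and the interaction 1 without the filter. In fits that left out 1 library the combination gave 0 to 29 against IgG, 0 to 10 against A2V and 1 to 32 against anti-CD40.

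In macrophages the combination against IgG gave 20 genes without the filter, 20 with the replicate block, 11 with only the 2 groups and 13 without the library that stood apart. Against A2V it gave 2 without the filter and 0 with the replicate block, a pseudocount of 0.1, only the 2 groups or without the library that stood apart. Against anti-CD40 it gave 0 with only the 2 groups and 0 without the library that stood apart. Anti-CD40 against IgG gave 1 without the filter, 0 with the replicate block and 5 without the library that stood apart, and A2V against IgG gave 4 with the replicate block and 1 with only the 2 groups. In fits that left out 1 library the combination gave 11 to 96 against IgG, 0 to 58 against A2V and 0 to 48 against anti-CD40.

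In CD8 T cells A2V against IgG gave 1 gene with scaling, 1 with the replicate block and 3 with the macrophage covariate, and the combination against anti-CD40 gave 3 with the replicate block. In CD4 T cells the combination against IgG gave 4 without the filter, 2 with the replicate block, 2 with a pseudocount of 0.1, 0 with only the 2 groups, 4 without the library that stood apart and 5 with the macrophage covariate. Against anti-CD40 it gave 1 with the replicate block, and 0 without the filter, with only the 2 groups, without the library that stood apart or with the macrophage covariate. Anti-CD40 against IgG gave 2 without the filter, 3 with the replicate block, 2 with a pseudocount of 0.1, 5 with only the 2 groups and 1 without the library that stood apart, and A2V against IgG gave 2 without the filter.

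For the replicate block, taken from the order of library numbers, the mean correlation of libraries within a set, after removal of the treatment mean, was 0.07 in endothelial cells, 0.06 in macrophages, 0.19 in CD8 T cells and 0.18 in CD4 T cells, against -0.02, -0.02, -0.06 and -0.06 between sets. The closest library of another treatment was of the same set for 7 of 15, 7 of 16, 10 of 16 and 9 of 16 libraries. In each gate this was more often than an even spread over the sets would give, though the excess was not tested. The main model, with treatment alone, leaves out any such structure by set, and whether the sets are batches stays open. The macrophage grouping that called 2233 genes followed these sets. With the replicate block, Il12b and Ccl24 missed the threshold for anti-CD40 against IgG in macrophages (adjusted p = 0.0527 and 0.0689), Ubd for the combination against IgG in endothelial cells (0.0503), and Cxcl13, Pla2g2d and Il12b for the combination against A2V in macrophages (0.113 each). So did Chst2 (0.0689), Tspan32 (0.0772), Serpinb9 (0.0561), Ly6i (0.0896), Il2rg (0.0961) and Il7r (0.0941) in macrophages, Fkbp14 against IgG and A2V (0.0503 and 0.0881) and H19 (0.125) in endothelial cells, and Olfr110 (0.0908) and Zfp791 (0.0659) in CD4 T cells. Against IgG, Cxcl13, Pla2g2d, Il12b, Nr1h3, Irg1 and Spic still passed in macrophages. In the CD4 gate, with the macrophage covariate, the activation call of anti-CD40 against IgG was lost (adjusted p = 0.141), as was the helper list call of the combination against anti-CD40 (0.697).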

Other observations

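Both paragraphs on biology and the comparison of red cell genes were chosen after the data were seen. In endothelial cells with the combination against IgG, T cell chemokines passed as a list (median 0.17, mean 0.39, adjusted p = 0.00345, and adjusted p = 0.522 with an estimated correlation), with Cxcl9, Cxcl10, Cxcl11, Ccl5 and Cxcl12 rising when adjusted over the list alone, against 0 over all genes. That call ended without combination replicate 2 (adjusted p = 0.0503) or combination replicate 3 (0.0544), and the count of 5 was 3 without combination replicate 2 or IgG replicates 2 or 4 and 2 without combination replicate 3.

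In CD8 T cells with the combination, cell cycle genes were higher than with IgG in 29 of 30 cases (median 0.5, adjusted p = 0.000722, and adjusted p = 0.663 with an estimated correlation), and the call ended without combination replicate 4 (adjusted p = 0.0667). Mcm2, a helicase subunit of DNA replication, was at 24.1 ± 13.2 RPKM with IgG and 42.6 ± 4.78 with the combination (n = 4 each).

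The mean log2 level of 3 red cell genes was lower with A2V than with IgG in libraries of each of the 4 gates. It was 4.77 ± 0.95 against 7.59 ± 1.11 (SD, n = 4 each) in endothelial cells, 2.99 ± 1.03 against 6.25 ± 1.13 in macrophages, 3.8 ± 1.54 against 7.57 ± 1.17 in CD8 T cells and 4.1 ± 1.6 against 7.4 ± 1.15 in CD4 T cells. Each of these 4 differences had a two-sided exact permutation p of 0.0286, the smallest possible with 70 splits, and a BH value of 0.0572 over 16 comparisons. With the combination the difference from IgG was -2.09 in macrophages, -2.9 in CD8 T cells and -3.04 in CD4 T cells (exact permutation p = 0.0286 each) and 0.01 in endothelial cells (exact permutation p = 1). With anti-CD40 alone it was 0.5, 0.06, -0.23 and 0.07 in endothelial cells, macrophages, CD8 T cells and CD4 T cells, with an exact permutation p of 0.6 or higher in each. The gates were not independent readings. Between libraries of the same run of 4 library numbers, the level correlated with a Pearson r from 0.84 (endothelial and CD4 T cells, n = 15) to 0.98 (macrophages and CD8 T cells, n = 16). The permutation p of these was 1e-04 and 1e-05 (BH 1e-04 and 2e-05 over 12 relations, 100000 permutations), the Spearman rho 0.75 and 0.96 (permutation p 0.002 and 1e-05, BH 0.002 and 2e-05), and r without the 2 farthest libraries 0.72 and 0.98. Within treatments r lay between 0.8 and 0.96 for the 6 pairs of gates.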
